A study of Mus musculus with 6 samples.

How the data were processed

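H3K9ac, an acetylation of histone H3 found at active promoters and enhancers, was profiled by CUT&RUN in lung endothelial cells isolated from mice. CUT&RUN cuts and releases the DNA that lies under an antibody-bound protein with a nuclease, and the released fragments are sequenced. Per the labels, 3 libraries came from WT mice (Cre-negative) and 3 from CSE-KO mice (Cre-positive). CSE is cystathionine gamma-lyase, the enzyme encoded by Cth that makes cysteine from cystathionine. Libraries were made with a ThruPLEX DNA kit and sequenced as short paired-end reads on a NextSeq instrument, per the labels' protocols. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

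The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.11a, Picard 3.1.1, featureCounts and DESeq2 1.36.0, without their order or settings. The peak caller and the treatment of reads that map to several places are not given in the sources used here. The authors deposited 1 table with a row per peak, and its whole-number columns hold the raw count of reads per peak and library. Per the file headers it also holds normalized values for each library, RPKM values, and the authors' log2 fold change, its standard error, and p-values before and after adjustment. The deposited normalized columns carry TMM in their names, but each equals the count divided by 1 factor per library, and their mean is the authors' mean value of the peak, as in a DESeq2 size-factor normalization. They were not used for tests. The names of the deposited normalized and RPKM columns carry a different numeric prefix for WT than for CSE-KO libraries. Its meaning is not given in the sources used here, and a batch that follows the groups cannot be told apart from them.

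The deposited table held 17901 rows, while the row identifiers reached 23867, so it holds 75.0% of the numbered peaks. The smallest sum of RPKM over the 6 libraries was 167, as a filter on low peaks would leave. The library totals implied by the authors' RPKM values are larger than the sums over the rows, and the rows hold 92.0% to 94.4% of them. Counts were therefore scaled to the sums over the rows, and the implied totals were tried as an alternative chosen after seeing the data.

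The notes name the genome build mm39, but the coordinates of the table follow GRCm38 (mm10). The transcription start implied by the peak's centre and its deposited distance was compared with a RefSeq gene table on GRCm38.p6, where 11058 of 11191 gene symbols were found. The implied start lay within 100 bp of the first or last base of the gene on that assembly for 66.6% of 17674 peaks, with a median gap of 5 bp, and 99.7% of the 7929 promoter peaks lay in or next to their gene. Coordinates are given as in the deposited table, on GRCm38. Gene names, the nearest transcription start, introns, exons and repeat elements are those of the authors' deposited annotation. No genome sequence was used here.

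Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr with a minimum count of 10, TMM factors, glmQLFit and glmQLFTest with the group as the sole term, two-sided, with Benjamini-Hochberg adjustment over the tested peaks and a threshold of 0.05. The filter left 16134 peaks and removed 1767. Standard errors (SE) of a log2 fold change were taken from the quasi-likelihood F statistic. Levels are CPM (counts scaled to a common library size after TMM), as mean ± SD over the 3 libraries of a group. Of the 6 pairs of libraries within a group, none agreed within sampling noise (chi-square per degree of freedom 1.85 to 2.14), so each counted as 1 replicate. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

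The 21 gene lists were tested on 1 promoter peak per gene, the one with the highest mean within 1 kb of the transcription start or annotated as promoter, over 7638 genes. The distance is that of the peak's centre, so a broad peak that covers a start could count as distal and be left out. The tests were camera with a preset inter-gene correlation of 0.01, camera with an estimated correlation, and fry (limma 3.58.1), with Benjamini-Hochberg adjustment over the lists with 2 or more tested members. Named genes are Cth, the up to 10 called peaks with the largest change in each direction that had at least the median abundance, a named gene and groups that did not overlap, and up to 4 members per list with the smallest unadjusted p. The value of 1 list member that this rule takes is not reported here. Called peaks outside this rule are named too and were chosen after their values were seen.

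Alternatives were size factors of the RLE type, library size alone, voom (limma) with quantile normalization and with TMM, the Wald test of DESeq2 1.42.0, no filter, a mean count of 50 or more, robust dispersion, a test against a fold of 1.2, a replicate block, and each library left out in turn. The tests were run on simulated counts with the means, depths and dispersion trend of these libraries, with 200 peaks changed in each of 5 simulations. At 3-fold, 81.6% of the changed peaks were called, at 2-fold 44.4% and at 1.5-fold 8.80%. On average 5.20 unchanged peaks were called per simulation. With fewer changed peaks the adjustment is stricter, so these shares likely overstate detection where few peaks change. Input DNA and gene expression were not analysed here.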

Results

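H3K9ac was measured by CUT&RUN in isolated mouse lung endothelial cells of 2 groups, 3 WT and 3 CSE-KO libraries, to ask how loss of the cysteine-producing enzyme CSE alters histone acetylation at endothelial loci. The total count over the peaks was 676056, 313610 and 610922 in WT replicates 1 to 3 and 1173016, 679938 and 685131 in CSE-KO replicates 1 to 3. Every CSE-KO library was deeper than every WT library (exact permutation test, two-sided, p = 0.10, the smallest that 3 against 3 allows). The median tested peak had a mean count of 32 per library, and the median SE of a log2 fold change was 0.30. Peaks within 1 kb of a transcription start held 59.8% ± 0.21 of the counts in WT and 59.5% ± 0.067 in CSE-KO (SD, n = 3 each; exact permutation test, two-sided, p = 0.20). Pearson's r of log2 CPM across peaks was 0.789 to 0.886 within groups and 0.783 to 0.863 between groups. The first principal component held 35.8% of the variance and set apart WT replicate 2, the shallowest library. The second held 20.4%, with the WT libraries between -33.2 and 6.62 and the CSE-KO libraries between 15.04 and 22.1. The groups did not overlap on either component (exact permutation test, two-sided, p = 0.10 for each, the smallest that 3 against 3 allows).

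Cth, the gene of CSE, had no peak in the table used here. None of the 17901 rows was assigned to Cth and none overlapped the gene, and the nearest row, at Srsf11, lay 106 kb away. H3K9ac at the targeted gene is therefore not analysed here and does not check the labels.

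The H3K9ac signal fell in CSE-KO cells at murine leukemia virus (MuLV) proviral elements, repeats left in the genome by past retroviral infection. Input DNA and genotypes were not analysed here, so a loss of the mark cannot be told apart from proviral DNA that the CSE-KO mice lack. All 6 peaks annotated as the internal part of this element (MuLV-int) fell. They lie at 4 loci. The peaks made up 0.306% of the counts in WT and 0.0077% in CSE-KO libraries. On chromosome 8, 3 of them span 8071 bp between Tubb3, a tubulin of neurons, and Def8. The most abundant, an intergenic peak at chr 8, 123431966 to 123434265, went from 1154 ± 293 CPM in WT to 20.5 ± 9.13 in CSE-KO (SD, n = 3 each), a log2 fold change of -5.84 (SE 0.19, adjusted p = 9.05e-29, edgeR).

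The other peaks of the chromosome 8 locus fell too. The peak at 123429220 to 123429897, also nearest to Def8, had a log2 fold change of -6.57 (SE 0.31, edgeR adjusted p = 2.33e-22). The peak at 123426194 to 123428184, nearest to Tubb3, went from 936 ± 189 to 23.8 ± 16.9 CPM (log2 fold change -5.37, adjusted p = 2.56e-26). On chromosome 1, a peak upstream of Fcrla, an Fc receptor-like gene of B cells (170944143 to 170945757), went from 607 ± 94.0 to 17.0 ± 7.31 CPM (log2 fold change -5.18, SE 0.20, adjusted p = 3.36e-26). Another, 537 kb away near Alyref2, an mRNA export factor gene (171482709 to 171484972), went from 157 ± 34.6 to 14.6 ± 3.27 CPM (log2 fold change -3.43, SE 0.29, adjusted p = 1.16e-12). A peak of low abundance in intron 3 of AI506816 on chromosome 5 (23705356 to 23705821), outside the rule for named genes and chosen after its values were seen, went from 26.9 ± 8.10 to 2.96 ± 5.12 CPM (log2 fold change -3.28, adjusted p = 0.045). The AI506816 call was lost without WT replicate 1 (adjusted p = 0.12), WT 2 (0.22), WT 3 (0.26), CSE-KO 1 (0.56) or CSE-KO 2 (0.31), and with the DESeq2 Wald test (1.00, the highest of its alternatives). Proviral copies can be near-identical, though their sequences were not compared here. Reads of one copy may then be counted at another, so the loss at a single locus is uncertain.

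**Figure D1:**
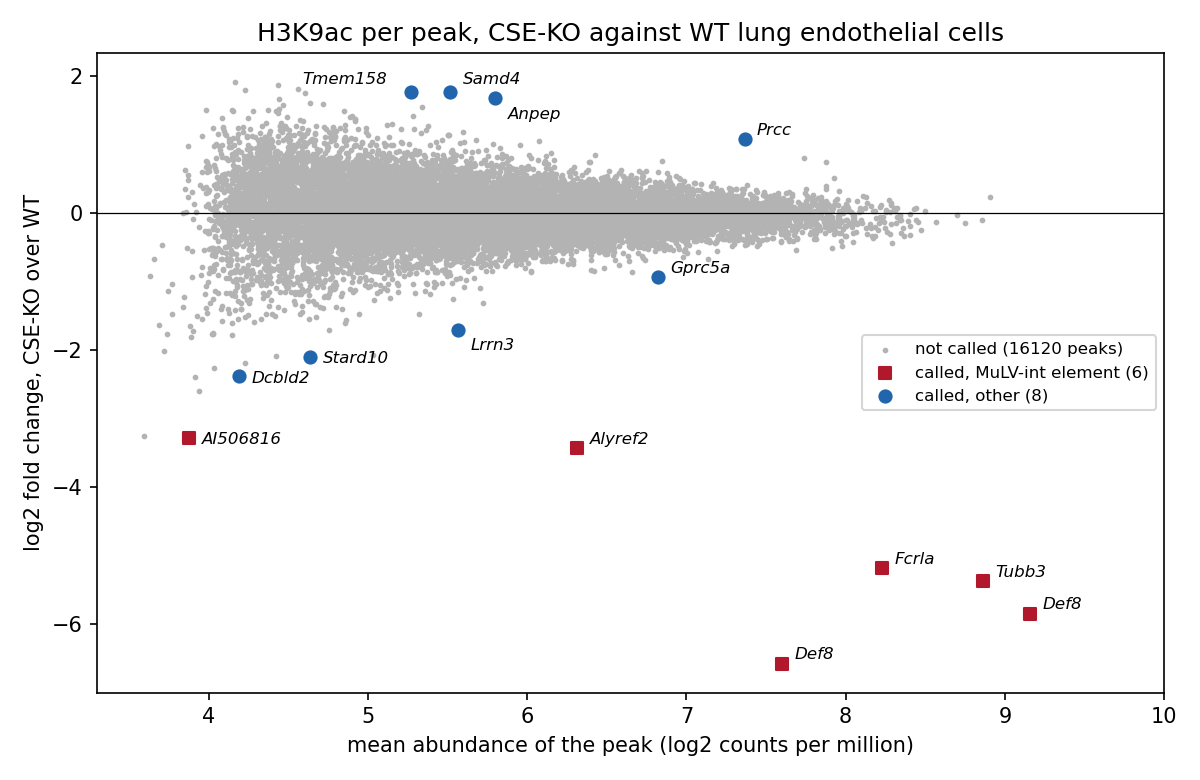
Each point is 1 of the 16134 tested peaks, with its mean abundance (log2 CPM) on the horizontal axis and its log2 fold change, CSE-KO over WT, on the vertical axis. Squares are the 6 called MuLV-int peaks, between -3.28 and -6.57, and large dots the 8 other called peaks, named by their nearest gene.

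Outside the provirus, 8 peaks changed, 4 higher and 4 lower in CSE-KO. H3K9ac rose about the start of Prcc, a gene known from its fusion to TFE3 in renal carcinoma, and within Anpep, the gene of the membrane peptidase CD13. The Prcc peak lies in exon 1 (chr 3, 87884473 to 87885929) and went from 101 ± 3.59 CPM in WT to 214 ± 15.5 in CSE-KO (SD, n = 3 each), a log2 fold change of 1.08 (SE 0.17, adjusted p = 2.22e-04, edgeR). The Anpep peak lies in intron 15 (chr 7, 79828798 to 79830237) and went from 22.5 ± 5.19 to 75.1 ± 10.0 CPM (log2 fold change 1.68, SE 0.31, adjusted p = 0.0044). H3K9ac fell in intron 1 of Gprc5a, an orphan G protein-coupled receptor gene induced by retinoic acid (chr 6, 135065519 to 135067180), from 144 ± 38.1 to 77.8 ± 2.25 CPM (log2 fold change -0.93, SE 0.20, adjusted p = 0.042). The Anpep call was lost without WT replicate 3 (adjusted p = 0.050) or CSE-KO replicate 1 (0.098). The Gprc5a call was lost without WT 1 (0.20), WT 3 (0.49), CSE-KO 1 (0.26), CSE-KO 2 (0.21) or CSE-KO 3 (0.25).

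The remaining called peaks were of lower abundance, lay away from promoters and were chosen after their values were seen. An intergenic peak upstream of Samd4, an RNA-binding protein gene (chr 14, 46872784 to 46873752), rose from 17.1 ± 3.45 to 59.6 ± 27.4 CPM (log2 fold change 1.77, adjusted p = 0.031, edgeR). One upstream of Tmem158, a membrane protein gene (chr 9, 123285088 to 123285809), rose from 15.8 ± 5.84 to 51.6 ± 8.50 CPM (log2 fold change 1.76, adjusted p = 0.042). A peak in an L1 element nearest to Lrrn3, a leucine-rich repeat gene (chr 12, 41777930 to 41778316), fell from 72.8 ± 11.5 to 24.0 ± 13.9 CPM (log2 fold change -1.70, adjusted p = 0.019). Its deposited distance to the Lrrn3 start is -292066 bp, so the gene name marks the position only. L1 is a repeat too, and the treatment of reads that map to several places is not given. Without input DNA or genotypes, a loss of the mark cannot be told apart from absent DNA at this L1 peak either. Intergenic peaks nearest to the lipid transfer gene Stard10 (chr 7, 101310494 to 101310817; log2 fold change -2.09, adjusted p = 0.042) and to Dcbld2 (chr 16, 58349847 to 58350112; -2.38, adjusted p = 0.045) fell too. With the MuLV-int peaks left out of the fit, a step chosen after seeing the data, Prcc (adjusted p = 0.0012), Anpep (0.016) and Lrrn3 (0.048) remained, while Samd4, Tmem158, Stard10, Gprc5a and Dcbld2 lay between 0.067 and 0.080. With these peaks left out of the adjustment alone, also chosen after seeing the data, Lrrn3 did not pass (adjusted p = 0.0501, edgeR), while Prcc (0.0013) and Anpep (0.015) did. The Wald test of DESeq2 called Prcc and Anpep alone of the 8. The Lrrn3 call was lost without WT replicate 3 (adjusted p = 0.33), CSE-KO 1 (0.49) or CSE-KO 3 (0.11). The Samd4 call was lost without any library but CSE-KO 2 (0.099 to 0.63), Tmem158 without any but WT 2 (0.15 to 0.31), Stard10 without any but CSE-KO 1 (0.099 to 0.33) and Dcbld2 without any library (0.12 to 0.33).

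**Figure D2:**
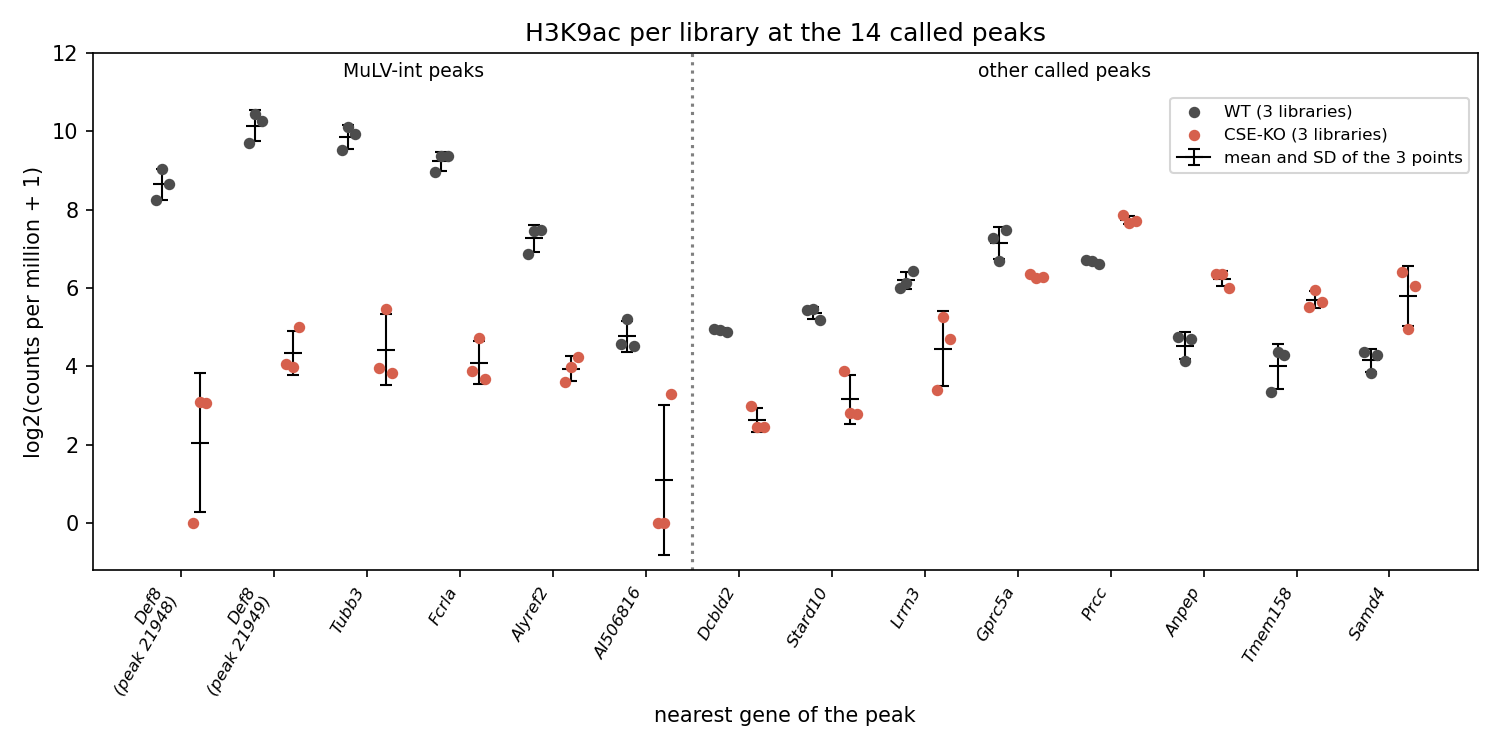
Points are the log2(CPM + 1) of each library at the 14 called peaks, named by their nearest gene, with WT in grey and CSE-KO in red; bars show the mean and SD of the 3 points. The WT and CSE-KO libraries do not overlap at any of the 14 peaks, and at Prcc the WT mean is 101 and the CSE-KO mean 214 CPM.

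Few single peaks changed across the genome. Of 16134 tested peaks, 14 changed (edgeR), 4 higher and 10 lower in CSE-KO. The median log2 fold change was -0.00034, 50.1% of peaks had a fitted value below 0, and 83.5% lay within 0.5 of 0. The scaling between libraries itself sets the median near 0. A change of the mark over all peaks alike could therefore not be seen with any scaling used here. At an unadjusted p under 0.05 edgeR gave 1142 peaks (7.08%; 485 higher, 657 lower), voom 1250 with TMM and 1262 with quantile normalization, and the Wald test of DESeq2 566, while 807 would be due to chance. The groups did not overlap at 13.0% of peaks, where chance gives 10%. The count of 14 went to 7 without WT replicate 3 (2 higher, 5 lower), to 8 without CSE-KO replicate 1 (1 and 7) and to 9 without CSE-KO replicate 3 (2 and 7). At this depth 44.4% of simulated 2-fold changes were called, so smaller changes at single peaks were mostly not detectable.

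Both promoter and distal peaks were called. Promoter peaks had their centre within 1 kb of a start or a promoter annotation, so some broad peaks over a start counted as distal. Among 7784 tested promoter peaks, Prcc rose and Gprc5a fell, and among 8350 distal peaks 3 rose and 9 fell, with the 6 proviral peaks among the latter. With 2 promoter calls, the comparison of gains and losses between the classes could not pass (Fisher's exact test, two-sided, p = 0.51, where the smallest possible is 0.066). Over all tested peaks, the share called was lower at promoters than at distal peaks (Fisher's exact test, two-sided, p = 0.014). The 6 proviral peaks among the distal calls lie at 4 loci and may share reads, so they may not be independent. Outside the provirus, 2 of 7784 promoter and 6 of 8344 distal peaks were called (Fisher's exact test, two-sided, chosen after seeing the data, p = 0.29). The median log2 fold change was -0.018 at promoters and 0.025 at distal peaks.

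Promoters of endothelial identity genes did not move together. The list, transcription factors and surface proteins that mark endothelial cells, had 25 tested promoter peaks, of which 12 lay below 0, with a median log2 fold change of 0.01 (camera adjusted p = 0.86). With 1 library left out in turn the median lay between -0.02 and 0.05, and the range beside each list median that follows is of the same kind. The mean level of its peaks was 137 ± 9.20 CPM in WT and 132 ± 8.37 in CSE-KO (SD, n = 3 each; exact permutation test, two-sided, p = 0.50). None rose or fell, adjusted over all peaks or adjusted over the list alone, and 3 had an unadjusted p under 0.05. Cdh5, the endothelial cadherin, had 255 ± 30.2 and 194 ± 2.34 CPM in WT and CSE-KO (log2 fold change -0.38, SE 0.15, adjusted p = 0.62). Ets1, an endothelial transcription factor, had -0.39 (SE 0.16), Tie1, a receptor of the angiopoietin pathway, 0.70 (SE 0.29), and Ets2 0.62 (SE 0.32), each with an adjusted p of 0.64 or more. The list test left out broad peaks over the starts of Sox7 and Clec14a, whose centres lay over 1 kb away. Chosen after their values were seen, these had -0.34 (SE 0.14, edgeR adjusted p = 0.64) and 0.48 (SE 0.23, adjusted p = 0.69). Among the 7638 genes with a tested promoter peak, 1 was lost and 1 gained, neither of them a list member, too few to test lists for enrichment.

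Of 54 angiogenesis genes, 43 had a peak but only 13 a tested promoter peak, so the values below cover a part of the list. Of 13 tested promoters of angiogenesis genes, 10 lay below 0 (median log2 fold change -0.16, range -0.23 to -0.08, camera p = 0.039, adjusted p = 0.22; p = 0.19 with an estimated correlation). The median was -0.08 without CSE-KO replicate 1 (camera adjusted p = 0.55) and -0.23 without CSE-KO replicate 2 (camera adjusted p = 0.055). It was -0.07 over all peaks of each gene (camera adjusted p = 0.97). None changed, adjusted over all peaks or adjusted over the list alone. Notch4, an endothelial Notch receptor, had 75.0 ± 12.3 CPM in WT and 46.3 ± 14.7 in CSE-KO (log2 fold change -0.68, SE 0.27, adjusted p = 0.64, edgeR). Bmpr2, a BMP receptor mutated in pulmonary hypertension, had -0.45 (SE 0.23), Hif1a, a hypoxia regulator, -0.40 (SE 0.20) and Hlx -0.61 (SE 0.41). The lung capillary list held 26 genes, of which 4 had a tested promoter. In it, 3 of 4 tested promoters lay below 0 (median -0.13, range -0.34 without WT replicate 1 to 0.14 without WT replicate 2, adjusted p = 0.67), with Rasgrp3 at -0.34 (SE 0.17), Calcrl at 0.43 (SE 0.28), Foxp1 at -0.21 (SE 0.49) and Itga1 at -0.05 (SE 0.32). The signs at Foxp1 and Itga1 turned under some alternatives. The arterial, venous and lymphatic list of 25 genes had 3 tested promoters (median 0.21, range -0.00047 without WT replicate 3 to 0.36 without WT replicate 1, adjusted p = 0.38). Mmrn1, a lymphatic marker, had 32.0 ± 13.3 CPM in WT and 61.9 ± 5.62 in CSE-KO (log2 fold change 1.06, SE 0.32) and passed in the edgeR test adjusted over the list alone (adjusted p = 0.0047) but not over all peaks (adjusted p = 0.37). Ephb4, a venous receptor, had 0.21 (SE 0.22) and Vcam1, an adhesion molecule, -0.68 (SE 0.45).

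Genes of the response to amino acid shortage through ATF4 had the smallest p of the lists by camera on promoter peaks. Only 2 of 15 promoters lay below 0, the median log2 fold change was 0.20, and the list did not pass (camera p = 0.0066, adjusted p = 0.11; p = 0.044 with an estimated correlation, adjusted p = 0.53). The median was 0.09 without WT replicate 3 and 0.11 without WT replicate 2, and 0.07 over all peaks of each gene (camera adjusted p = 0.97). With single libraries left out, the camera adjusted p lay between 0.055 (without CSE-KO replicate 2) and 0.44 (without CSE-KO replicate 1). No member was called, adjusted over all peaks or adjusted over the list alone. Nupr1, a stress-induced regulator, had 24.1 ± 3.85 CPM in WT and 41.3 ± 5.42 in CSE-KO (log2 fold change 0.75, SE 0.35, adjusted p = 0.68, edgeR). Psat1, an enzyme of serine synthesis, had 0.44 (SE 0.23), Eif4ebp1, a repressor of translation, 0.26 (SE 0.20) and Cebpg 0.22 (SE 0.20).

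The lists closest to cysteine use did not pass either. Transsulfuration and sulfide genes had 6 of 12 promoters below 0 (median 0.02, range -0.08 to 0.10, camera adjusted p = 0.43), with Mpst, which releases sulfur from mercaptopyruvate, at 0.64 (SE 0.29), Got1 at -0.29 (SE 0.21), Ethe1 at 0.62 (SE 0.49) and Prdx4 at 0.38 (SE 0.31). Amino acid and cystine transporters had 5 of 14 below 0 (median 0.06, range -0.02 to 0.12, adjusted p = 0.43). Slc7a7 was at 0.42 (SE 0.27), Slc1a5 at 0.62 (SE 0.53), Slc7a5 at 0.34 (SE 0.34) and Slc38a1 at -0.46 (SE 0.49). The NRF2 and glutathione list had 7 of 19 below 0 (median 0.10, range 0.05 to 0.13, adjusted p = 0.38). Nfe2l2, the gene of NRF2, had 230 ± 7.56 CPM in WT and 175 ± 23.2 in CSE-KO (log2 fold change -0.40, SE 0.15, adjusted p = 0.60), while Gclm, a subunit of the first enzyme of glutathione synthesis, had 0.39 (SE 0.22), Srxn1 0.35 (SE 0.20) and catalase, Cat, 0.52 (SE 0.30).

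Among genes of acetyl-CoA supply, 12 of 16 promoters lay below 0 (median -0.17, range -0.24 to -0.10 without CSE-KO replicate 1, camera adjusted p = 0.38). Slc16a1, a lactate and pyruvate transporter, had 83.1 ± 10.7 CPM in WT and 51.1 ± 11.6 in CSE-KO (log2 fold change -0.69, SE 0.26, adjusted p = 0.60, edgeR). Pdhx was at -0.34 (SE 0.20), Pdp1 at -0.51 (SE 0.37) and Acly, which makes cytosolic acetyl-CoA, at -0.31 (SE 0.28). Histone acetyltransferase and deacetylase genes had 15 of 24 below 0 (median -0.09, range -0.16 to 0.00027, adjusted p = 0.43), with the reader of acetylated histones Brd2 at -0.33 (SE 0.14), Ncoa1 at -1.08 (SE 0.44), Hdac4 at -0.28 (SE 0.22) and Hdac7 at -0.51 (SE 0.41). The tricarboxylic acid cycle and respiration list had 10 of 31 below 0 (median 0.07, range 0.02 to 0.08, adjusted p = 0.43). In it Mdh1, the cytosolic malate dehydrogenase, had 57.6 ± 9.80 and 28.5 ± 3.66 CPM in WT and CSE-KO (log2 fold change -1.02, SE 0.31, edgeR adjusted p = 0.061 adjusted over the list alone and adjusted p = 0.42 over all peaks), Cox5b 0.50 (SE 0.30), Sdhb 0.48 (SE 0.30) and Sdhc -0.44 (SE 0.31). Glycolysis and hypoxia genes had 9 of 19 below 0 (median 0.02, range 0.01 to 0.12, adjusted p = 0.43), with Eno1 at -0.38 (SE 0.20), Pfkfb3 at 0.57 (SE 0.40), Slc2a1 at 0.47 (SE 0.40) and Bnip3 at 0.51 (SE 0.44).

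Genes of the endothelial to mesenchymal transition had 9 of 10 promoters below 0 (median -0.12, range -0.24 to -0.10, camera p = 0.028, adjusted p = 0.22; p = 0.10 with an estimated correlation). Over all peaks of each gene the median was -0.0073 (camera adjusted p = 0.97). In the mixed test of fry this list had the smallest p of the lists (adjusted p = 0.15). Vim, the gene of vimentin, had 374 ± 33.9 CPM in WT and 300 ± 4.42 in CSE-KO (log2 fold change -0.32, SE 0.13, adjusted p = 0.64, edgeR). Zeb2, a transcriptional repressor, was at -0.60 (SE 0.26) and Snai2 at 0.46 (SE 0.34). Inflammation genes had 7 of 11 below 0 (median -0.06, range -0.21 to -0.04, adjusted p = 0.39), with the adhesion molecule Icam1 at -0.48 (SE 0.30), Stat3 at -0.31 (SE 0.20) and Tnfaip3 at -0.34 (SE 0.24). Cell cycle genes had 17 of 24 below 0 (median -0.07, range -0.15 to -0.02, adjusted p = 0.43), with Cdk4 at -0.32 (SE 0.21), Mcm2 at -0.56 (SE 0.39), Pcna at -0.40 (SE 0.30) and Cdkn1b at -0.31 (SE 0.24). Cytosolic ribosomal protein genes had 10 of 24 below 0 (median 0.05, range -0.04 to 0.05, adjusted p = 0.43), with Rps24 at 0.34 (SE 0.20), Rps15 at 0.26 (SE 0.16), Rplp2 at -0.35 (SE 0.24) and Rpl14 at 0.28 (SE 0.21).

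Markers of other lung cells had few peaks, while 40 of 43 endothelial identity genes had at least 1. Peaks were assigned to 4 of 20 fibroblast, 3 of 20 smooth muscle and pericyte, 2 of 28 leukocyte, 1 of 10 mesothelial and 8 of 24 epithelial markers. No promoter peak of the fibroblast, smooth muscle or mesothelial lists was tested. The leukocyte list had 1, at Cd14, with a log2 fold change of 0.29 (SE 0.33), and the epithelial list had 2, Etv5 at -0.44 (SE 0.23) and Abca3 at 0.41 (SE 0.31; list median -0.02, range -0.09 to 0.08, camera adjusted p = 0.80).

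Over all lists, none of the 17 with 2 or more tested members passed by camera, camera with an estimated correlation, fry or the mixed test of fry. At an unadjusted p under 0.05 there were 3, 1, 2 and 1 lists by these tests. The lists held 581 genes, and many of them had no tested promoter peak. Of 263 tested promoter peaks of list genes none was called by edgeR, DESeq2 or voom, and 15 had an unadjusted p under 0.05 (5.70%). In simulated counts with independent genes, a fall of all endothelial identity promoters by 0.2 on the log2 scale was called in 8 of 8 simulations, and the same fall of the angiogenesis promoters in 5 of 8. In the data the estimated inter-gene correlation was 0.13 for endothelial identity and 0.078 for angiogenesis. Correlated genes make such a fall harder to call, so the simulations likely overstate what could be detected.

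**Figure D3:**
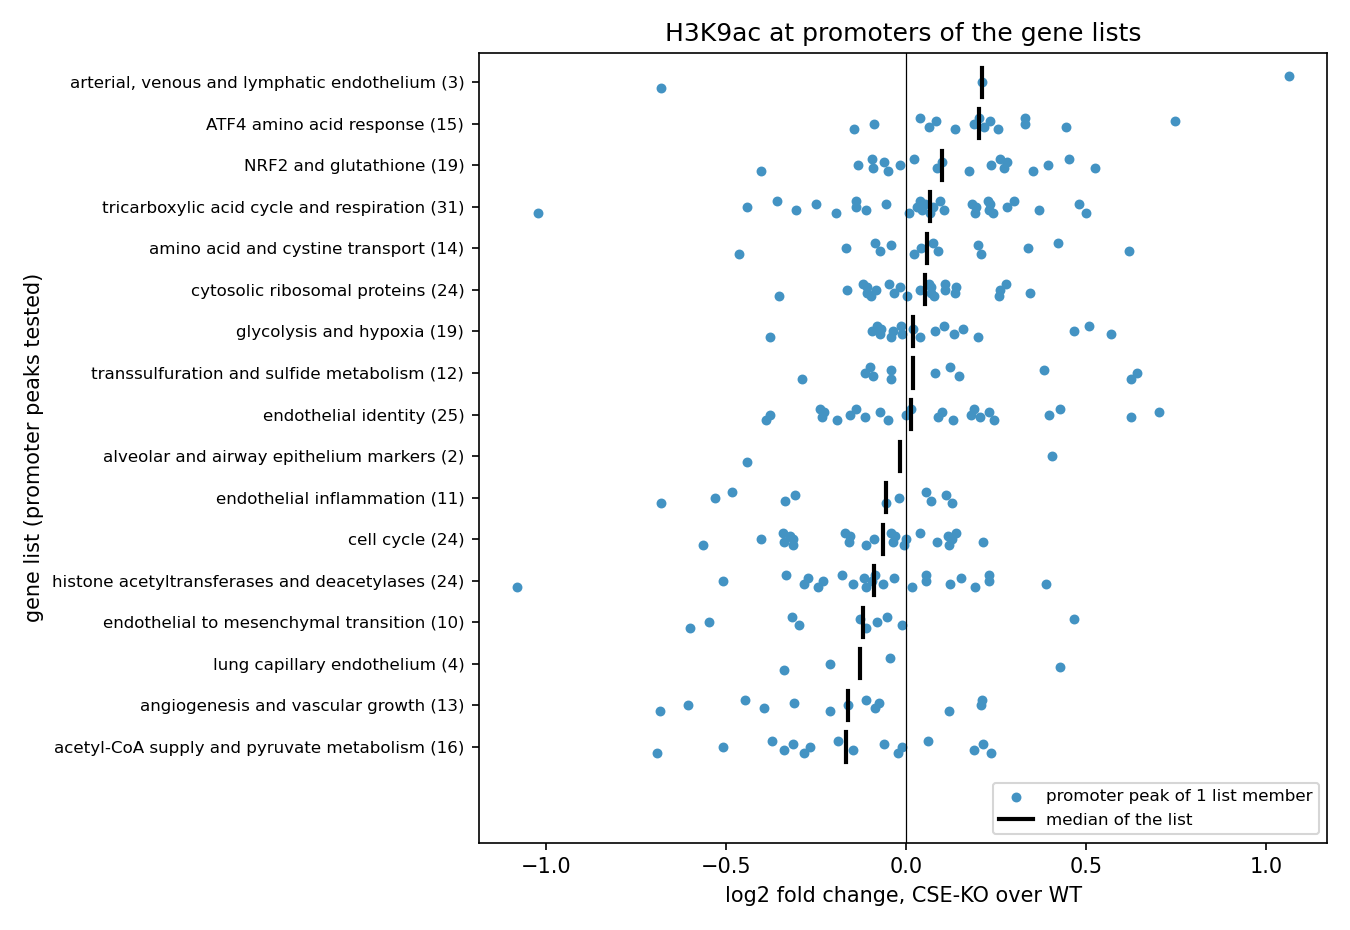
Points are the log2 fold changes, CSE-KO over WT, of the promoter peak of each list member, for the 17 lists with 2 or more tested members (number in brackets); black bars are list medians. The medians lie between -0.17 for acetyl-CoA supply and 0.21 for the arterial, venous and lymphatic list, which went to -0.10 without CSE-KO replicate 1 and -0.00047 without WT replicate 3, and no list passed its test.

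The authors' deposited table holds a test of the same counts. At an adjusted p under 0.05, the authors' deposited table has 10 peaks, 2 higher (Prcc and Anpep) and 8 lower in CSE-KO. All 10 were among the 14 called here, and Samd4, Tmem158, AI506816 and Dcbld2 were called here alone. The smallest adjusted p of the authors is 23812.5 times their smallest unadjusted p. Their adjustment thus ran over more peaks than the 16134 tested here, and the 10 and 14 calls are not at like numbers of tests. The log2 fold changes in the authors' deposited table and those fitted here had a Pearson's r of 0.999 across peaks, which are not independent replicates. An unadjusted p under 0.05 was held by 980 of the 17901 peaks of the authors' deposited table, where 895 would be due to chance.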

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

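The alternatives that leave out the MuLV-int peaks and that with RPKM-implied totals were chosen after seeing the data. The 14 changed peaks (4 higher, 10 lower) became 7 with the DESeq2 Wald test (2 and 5), 8 at a mean count of 50 or more (3 and 5), 8 in the test against a fold of 1.2 (2 and 6), 3 without the MuLV-int peaks (2 and 1) and 2 with these peaks left out of the adjustment alone (2 and 0). The last 2 alternatives leave out 6 calls by construction. At a mean count of 50 or more, Alyref2, AI506816, Dcbld2, Stard10, Lrrn3, Anpep, Tmem158 and Samd4 were not tested. Of the 14 calls, 6 were kept there, and 2 peaks were newly called. For the DESeq2 Wald test and the test against a fold of 1.2 the cause was not tested. Leaving out single libraries gave 7 to 13 changed peaks, 1 to 5 higher and 5 to 9 lower. The other alternatives gave 11 to 15. Similar counts hid some turnover of the 14 calls. Voom with quantile normalization kept 9 and made 5 new calls, voom with TMM kept 10 and made 3. Without WT replicate 1, 8 were kept and 4 were new. RLE size factors, robust dispersion and RPKM-implied totals kept all 14. Def8, Tubb3, Fcrla and Prcc were called in each fit that tested them, and Alyref2 in each of its 17; Anpep was called in 16 of 18, Lrrn3 in 14 of 18, Gprc5a in 9 of 19, Stard10, Tmem158 and Samd4 in 8 of 18, AI506816 in 8 of 17 and Dcbld2 in 4 of 18, and none turned its sign.

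The share of tested peaks below 0, 50.1%, was 47.1% with library size only, 48.3% with voom and quantile normalization, 49.6% with voom and TMM, 49.7% without a filter, 49.8% at a mean count of 50 or more and 49.7% with the replicate block; single libraries left out gave 49.3% to 50.1%. No list passed in any of its 12 alternatives, but with single libraries left out the medians of all 17 lists tested moved by over 1.5 times and those of 8 turned sign. The p of gains and losses by promoter and distal class ranged from 0.055 to 1 and says little of stability, since a p under 0.05 was possible only with voom and TMM (0.20), at a mean count of 50 or more (0.46), with the replicate block (0.53) and without WT replicate 2 (0.51). None of the authors' 10 calls was lost at a minimum fold of 1.5. Of 65 list members taken by the rule for named genes, 4 turned sign, none of them called: Pdp1 (-0.89 to 0.039 with single libraries left out, above 0 without WT replicate 2), Foxp1 (-0.74 to 0.26, above 0 without WT 2 and without CSE-KO 3, and 0.020 with voom and TMM), Itga1 (-0.27 to 0.11, above 0 without WT 2, WT 3 or CSE-KO 1) and Ephb4 (-0.00047 to 0.36, below 0 without WT 3).

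The same replicate number did not pair libraries: deviations from the group means correlated at 0.065, 0.014 and 0.0051 for numbers 1 to 3, and WT 2 and WT 3 each correlated better with another number. With the replicate block 15 peaks changed (6 higher, 9 lower). Alternatives planned for normalized values were not run, since counts were deposited, and those for Cth had no row. Depth limits single peaks, with 44.4% of simulated 2-fold changes called, which likely overstates detection in the data. It was not compared with other limits: without WT replicate 2, the shallowest at 313610 counts, 13 peaks changed, and without WT 3, 7.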

Other observations

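Of the tests below, those of proviral insertion and silencing and every count of splits except that of all changed peaks were chosen after the result was seen. Promoters included, 702 tested peaks were assigned to genes of the lists. None was called by edgeR, and 49 had an unadjusted p under 0.05, 23 higher and 26 lower in CSE-KO, among them the 15 promoter peaks of list members. Over all tested peaks the share with such a p was 7.08%, so peaks of list genes do not stand out. The examples that follow were chosen after their values were seen. The smallest p lay upstream of Slc3a1, a subunit of cystine transporters, with 59.0 CPM in WT and 21.7 in CSE-KO (log2 fold change -1.47, SE 0.37, adjusted p = 0.15). Both peaks of Mmrn1 with an unadjusted p under 0.05 lay above 0 (1.06 and 0.93, adjusted p = 0.37 and 0.45), and an exon peak of Nr2f2, a regulator of venous and lymphatic fate, lay below 0 (-0.54, SE 0.16, adjusted p = 0.37). At Kdr, the main VEGF receptor of endothelium, a distal peak was at -1.08 (SE 0.51, adjusted p = 0.68), and at Tek, an angiopoietin receptor, one was at 1.27 (SE 0.49, adjusted p = 0.61).

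The loss at the MuLV-int peaks was weighed against explanations. Other endogenous retroviral peaks argue against a general loss over such elements (median log2 fold change 0.00061, 95% bootstrap interval -0.047 to 0.052, 396 peaks). Of these, 175 are of the ERVL-MaLR family (median -0.024), which was added to the planned ERV1 (0.0077), ERVK (0.055) and ERVL (-0.053). These medians do not tell of a loss limited to elements like MuLV. The 17 other peaks within 100 kb, none of them called, argue against a loss of the whole region (median 0.056, interval -0.11 to 0.28). Both intervals resample peaks and hold no spread between libraries. A candidate explanation is that WT mice carry proviral insertions that the CSE-KO mice lack, as a difference in strain background would give. The highest CSE-KO library was at 11.3% of the WT mean at the 5 more abundant peaks and 32.9% at AI506816, but these low levels prompted the explanation, and silencing of the same proviruses in CSE-KO cells, with a median level of 2.67% left, would give them too. Absent DNA and silencing cannot be told apart at any of the 6 peaks without input or genotype data, and background is that C57BL/6 mice carry the ecotropic provirus Emv2 on distal chromosome 8.

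At an unadjusted p under 0.05, where chance gives 807 peaks, edgeR gave 1142, voom 1250 and 1262 and the DESeq2 Wald test 566, and the authors' deposited table holds 980 where chance gives 895. For the 1142 peaks a technical candidate is that libraries of the groups differ in promoter against distal enrichment. The median log2 fold change of promoter peaks lay below that of distal peaks (difference -0.043, 95% bootstrap interval -0.053 to -0.030). The difference is too small for the size set as a cause and not clearly under the size set against it. The interval resamples peaks and holds no spread between libraries, so this candidate stays open. Depth also follows the groups, since each CSE-KO library was deeper. The biological difference between WT and CSE-KO stays open too.

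The 6 libraries make 10 splits of 3 against 3, the real one included, too few for a share under 0.05. The real split called 14 peaks and the highest other 2. Outside the provirus it called 8 against 2, and with the MuLV-int peaks left out of the fit of each split 3 against 2. Higher peaks numbered 4 and lower peaks 10, where no other split had more than 1 in a direction, and in each of these counts 1 split, the real one, reached the real value. Peaks at an unadjusted p under 0.05 by edgeR numbered 1142 against 856. Gene lists passing numbered 0 in the real split and 1 in the highest other. With 0 in the real split, all 10 splits had as many by construction, so this count says nothing of chance.

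It was tested whether differences extend over neighbouring peaks, as a change of whole domains would give. Over 2578 pairs of neighbouring peaks at most 10 kb apart, without the MuLV-int peaks, Pearson's r of log2 fold changes was -0.033 in the real split and 0.090 in the highest of the other splits. The excess in the real split that such domains would give was not seen. The median SE of a log2 fold change was 0.30, and such noise draws r towards 0 with or without domains. The test therefore cannot decide on domains of small change.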
